A study of Drosophila melanogaster with 14 samples.

How the data were processed

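The 14 libraries were made from polyadenylated RNA of type II neural stem cells of the larval brain, with 1k to 2k cells per library per the labels' protocols. RNA was amplified with a whole-transcriptome kit (Discover-sc WTA Kit V2) and libraries were made with a transposase kit (TruePrep DNA Library Prep Kit V2), per the labels. Such a kit does not mark strand, so reads of a gene and of an antisense neighbour cannot be told apart. Nothing in the labels says that replicates came from separate animals or crosses, so p-values measure the spread between these libraries, which may be partly technical.

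The deposited values are raw counts per gene, a whole number for each library. Per the submitters' processing notes, Trim Galore 0.6.10, HISAT2 2.2.1, SAMtools 1.6 and featureCounts 2.0.3 were used with the dm6 genome. The gene annotation, the treatment of multi-mapping reads and whether reads or pairs were counted are not given in the sources used here. Between 61.5% and 70.4% of counts from 1 to 49 were even, as would arise where both mates of a pair were often counted, so counting intervals are too narrow by an unknown amount. The table held 17868 genes with no duplicated or empty name, of which 17161 were current symbols and 17809 matched 1 gene of the reference name table. Coordinates and exon overlap were taken from the BDGP6 annotation, the assembly that dm6 names. It may differ from the annotation used for counting.

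Samples were grouped by their titles, and each experiment was compared only with its own controls. Genes were kept with the edgeR expression filter (a minimum count of 10 and a minimum total of 15). Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with robust dispersion estimates, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM are TMM-normalised within an experiment. Standard errors are the log2 fold change divided by the square root of the F statistic. Differences between experiments were tested as contrasts in 1 fit of the 6 groups. Of gene lists, 30 were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, under which no list passed in any experiment, and with fry. Of the list entries, 8 matched no gene. Lists with fewer than 3 tested members had no list test. Overlaps were tested with Fisher's exact test.

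The samples, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Not among the fixed tests were fry and the list tests of differences between experiments. Named were the targeted gene, the 8 largest rises and 8 largest falls among changed genes with at least 10 CPM in the higher group, complete separation of the libraries and a symbol other than a CG or CR number or non-coding RNA name, and up to 4 changed members of each list with the smallest p, or 2 values where none changed. The genes dpn, ase, erm, pros, pnt and elav were given throughout, and in the HDAC1 experiment all 10 changed genes were named, a choice made after the values were seen. A fold against a group with no counts is a bound against 3 counts over the group. Intervals of ratios of counts are exact at 95% and cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Intervals of a ratio of spreads (1000 resamples) and of medians (5000 resamples) are 95% bootstrap intervals over genes. They do not cover the spread between libraries.

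Alternatives were RLE factors or library size only, no filter or a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, all 14 libraries in 1 fit, a minimum log2 fold change of 1 and each library left out. Counts divided by 2 were added after the excess of even counts was seen. The tests were tried on simulated counts drawn from the real means and dispersions with 200 genes changed. In the GAF experiment (9055 genes) 59% of 2-fold and 81% of 4-fold changes were called, with 13 unchanged genes called. The shares were 3% and 43% in the HDAC1 experiment (10299 genes, 2 unchanged called) and 59% and 84% in the Osa experiment (9156 genes, 13 unchanged called). Called genes had the simulated direction, and 1 raised list of 20 genes was found in each while 0 of 29 unchanged lists passed camera. Each gene was simulated independently, so camera was not tried on lists whose members move together. In the real data the estimated correlation reached 0.797 for ribosomal protein genes in the Osa experiment. Replicates of a group were compared before averaging: the median chi-square per gene with at least 100 counts in a pair was 7.52 to 28.8, and 132 for the HDAC1 RNAi pair, so no 2 libraries were alike within sampling noise. The most abundant transcript took 3.09% to 10.4% of a library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.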

Results

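Polyadenylated RNA was sequenced from type II neural stem cells of the Drosophila melanogaster larval brain, the neuroblasts that generate neurons and glia through intermediate neural progenitors. The series was made to ask what GAF, HDAC1 and Osa do in neural development. GAF (GAGA factor, gene Trl) is a DNA-binding protein of GA-rich promoters, HDAC1 a histone deacetylase and Osa a subunit of the BAP form of the SWI/SNF chromatin remodelling complex. There were 14 libraries in 3 experiments, each with its own controls: GAF RNAi (3 libraries against 3), HDAC1 RNAi (2 against 2) and Osa overexpression (2 against 2). Total counts ranged from 42372121 to 51505597 per library in the GAF experiment, from 34124750 to 35648398 in the HDAC1 experiment and from 31788351 to 34062172 in the Osa experiment. Expression is given in TMM-normalised CPM as mean ± SD. Log2 fold changes ± SE are from edgeR.

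The targeted genes were examined first. Osa lies on chromosome 3R from 17687818 to 17718350 (gene FBgn0261885, minus strand), shares 0% of its exonic bases with another gene, and rose from 148 ± 2.45 to 294 ± 8.12 CPM (n = 2 and 2, log2 fold change 0.99 ± 0.13, edgeR adjusted p = 0.0029). This is the direction of an overexpression, which is what the sample labels state, while the design text of the series speaks of a knockdown. In a fit of all 14 libraries, which takes its spread from every experiment, the same change did not pass (0.99, edgeR adjusted p = 0.0642). The common biological coefficient of variation was 0.39 in the HDAC1 experiment alone and 0.216 in the Osa experiment alone. HDAC1 lies on chromosome 3L from 4626734 to 4629467 (FBgn0015805, plus strand, 8% of exonic bases shared with an antisense RNA gene). The controls held 70.9 and 79.2 CPM of HDAC1, the library labelled HDAC1 RNAi replicate 1 held 59.7 and the library labelled HDAC1 RNAi replicate 2 held 34.8. The difference did not pass the test (−0.67 ± 0.39, edgeR adjusted p = 0.576). Without replicate 1 the HDAC1 fold change was −1.09 and passed (edgeR adjusted p = 0.00561). Trl lies on chromosome 3L from 14747929 to 14761049 (FBgn0013263, minus strand), and 77.8% of its 6254 exonic bases overlap exons of other genes on the same strand, mainly CG42507. Its count was 5.5 ± 0.794 CPM in controls and 5.21 ± 0.742 CPM in GAF RNAi (−0.08 ± 0.25, edgeR adjusted p = 0.843), so no fall was seen. How reads in shared exons were counted is not given, so how much of this count comes from Trl is unknown. A knockdown of Trl RNA is therefore neither shown nor excluded by these counts.

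**Figure D1:**
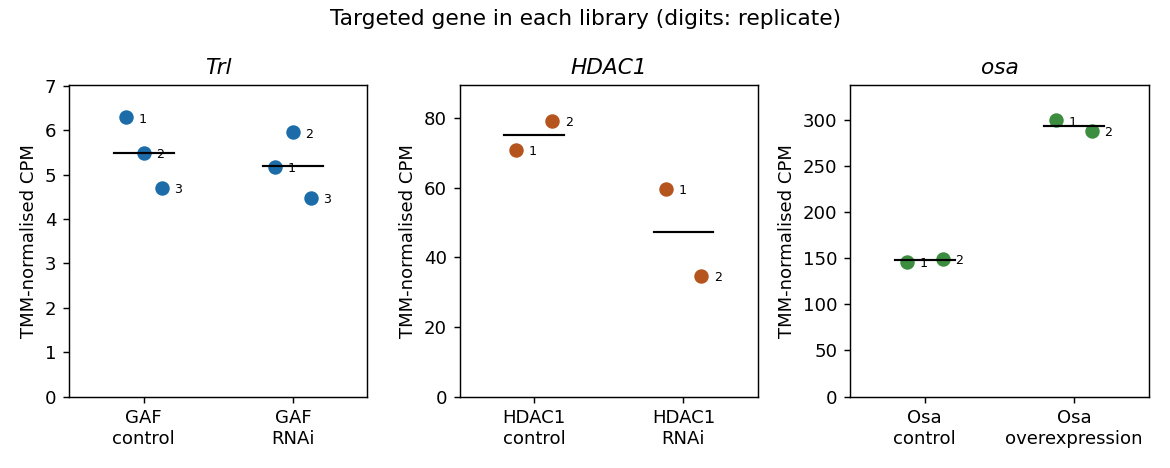
CPM (TMM-normalised within each experiment, linear axes from 0) of the targeted gene in each library, as points with the replicate number, with a line at the group mean. The osa points separate at 148 and 294 CPM on average, the HDAC1 RNAi points lie at 59.7 and 34.8 CPM below controls at 70.9 and 79.2, and the Trl points overlap.

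In the libraries labelled GAF RNAi some genes, glutathione S-transferase genes among them, were almost absent, and genes of progenitors and neurons were higher. Trl counts showed no fall, and whether these changes reflect GAF or the genetic background of the cross was not settled. GstE6, a glutathione S-transferase, fell from 214 ± 52.8 to 0.0143 ± 0.0249 CPM (n = 3 and 3), a ratio of 14800 with a counting interval of 4090 to 122000. Its cluster neighbours GstE7 and GstE8 fell from 27 to 0.113 and from 47.6 to 0.303 CPM, and reads shared among these similar genes make the split between them uncertain. Ugt302C1, a UDP-glycosyltransferase, fell from 13.9 ± 6.45 CPM to no counts, at least 660-fold against a floor of 3 counts over the group. Smaller falls were seen for aralar1, a mitochondrial aspartate-glutamate carrier (−6.57 ± 0.37), CHKov2 (−6.07), OtopLc (−5.45) and elB (−5.45). Among named genes of at least 10 CPM in the higher group, RpS10a, a paralog of the ribosomal protein gene RpS10b, rose most, from 0.765 ± 0.282 to 45.6 ± 0.328 CPM (59.8-fold, edgeR adjusted p = 9.88e-09). It was followed by the translation factor gene eIF4E3 (5.45 ± 0.69), RSG7 (4.34), the cuticle protein genes Ccp84Ad (3.96) and Ccp84Ab (3.68), Eglp4 (3.6), the neuronal RNA-binding protein gene Rbp9 (3.48) and ATPsynepsilonL (3.37). Of 9055 genes tested, 2573 changed, 1131 of them higher and 1442 lower, and 1090 of these changed at least 2-fold. The count was 1451 in a fit of all 14 libraries, and 1713 without control replicate 2 or 1593 without RNAi replicate 1. Of 106 named genes that changed, 77 kept their call in the fit of all 14 libraries.

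Genes of the neuronal lineage rose in GAF RNAi. Of 11 intermediate progenitor genes tested, 10 rose (11 adjusted over the list alone), among them ase (35.3 ± 8.2 to 90.1 ± 13.2 CPM), a proneural factor of progenitors, erm (4.79 ± 2.26 to 15.1 ± 1.6 CPM), which restricts progenitor potential, toy (2.04) and ham (1.58). Of 13 genes of ganglion mother cells and early neurons, 8 rose (10 adjusted over the list alone), with nerfin-1 up from 14.9 ± 6.07 to 70.6 ± 18.2 CPM, dap at 1.74, elav at 1.16 and tap at 1.02. Of 22 mature neuron genes, 15 rose and 1 fell (19 and 1 adjusted over the list alone), including nrv3 (2.21 ± 0.26), Syt1 (1.7 ± 0.25) and VGlut (2.34 ± 0.35). The list medians were 1.44, 1.16 and 1.55, with camera adjusted p of 1.13e-06, 1.52e-05 and 2.86e-08. With an estimated correlation these became adjusted p = 0.451, 0.469 and 0.469. The differentiation factor gene pros also rose, from 134 ± 49.1 to 495 ± 167 CPM (1.89 ± 0.41, edgeR adjusted p = 0.0247). Glia genes moved both ways: 4 of 18 rose, such as Eaat1 (1.84) and nrm (1.42), and 2 fell, nrv2 from 598 ± 53 to 45.9 ± 3.36 CPM and Tret1-1 (−1.76). Adjusted over the list alone 5 rose and 2 fell, and the list did not pass (camera adjusted p = 0.865). Of the markers of other tissues, Col4a1 of blood cells rose to 1.99 CPM, Lsp1gamma of the fat body to 28.2 CPM and bt of muscle to 2.73 CPM, each the 1 member of its list past the threshold, with 1, 2 and 1 adjusted over the list alone.

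Stem cell genes did not move as a group in GAF RNAi. Of 20, 4 rose and 5 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.865). The growth regulator Myc fell from 1510 to 549 ± 53.3 CPM (−1.46 ± 0.15) and btd fell by 0.82 on the log2 scale, while brat, a translational repressor that limits self-renewal, rose from 332 ± 63.4 to 920 ± 121 CPM and CycE rose by 0.43. The neuroblast factor gene dpn (−0.21 ± 0.17, edgeR adjusted p = 0.388) and pnt (0.34 ± 0.13, edgeR adjusted p = 0.0596) did not pass. Among 15 temporal patterning genes, 4 rose and 3 fell (4 and 4 adjusted over the list alone), with chinmo (−0.75) and lin-28 (−1.86) lower and Eip93F (0.84) and mamo (1.71) higher. Of 24 asymmetric division genes 3 rose (1 adjusted over the list alone), brat, pros and insc (0.47). The call of insc was lost with library size only (edgeR adjusted p = 0.0508), no filter (0.0639) or all 14 libraries in 1 fit (0.408). It was also lost without control replicate 2 (0.202) or 3 (0.103), or RNAi replicate 1 (0.0858), 2 (0.146) or 3 (0.104). Of 28 Notch pathway genes 6 rose and 2 fell, the same numbers adjusted over the list alone, with Brd (2.85) and neur (0.61) higher and Tom (−2.74) and fng (−2.31) lower. Cell cycle genes split into 6 higher, such as CycA (0.46) and CycB3 (0.64), and 3 lower, such as Cdk4 (−0.7), of 40 (5 and 2 adjusted over the list alone).

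Ribosome biogenesis and glycolysis genes fell in GAF RNAi, and transcripts of the mitochondrial genome rose. Of 29 ribosome biogenesis genes 20 fell (21 adjusted over the list alone), led by Non1 (560 ± 43.4 to 209 ± 8.11 CPM), the RNA polymerase I subunit genes RpI135 (−1.31) and RpI1 (−0.92), and bys (−0.76). Of 12 glycolysis genes 7 fell (11 adjusted over the list alone), among them Hex-A (−1.25), Pgi (−1.02), Pfk (−0.75) and Ald1 (−0.43). The list medians were −0.56 and −0.43 (camera adjusted p = 1.13e-06 and 0.00539), with adjusted p = 0.469 and 0.574 with an estimated correlation. Transcripts of the mitochondrial genome rose for 12 of 16 genes (14 adjusted over the list alone, median 1.03, camera adjusted p = 1.98e-10, adjusted p = 0.451 with an estimated correlation), with ND1 up from 62.1 ± 3.68 to 250 ± 37.3 CPM, COX3 at 1.11, ND4 at 0.95 and COX2 at 0.93. They made up 5.78%, 6.34% and 7.41% of counts in the controls and 9.55%, 9.89% and 11% in the RNAi libraries. Nuclear oxidative phosphorylation genes went both ways, 13 of 70 higher (COX7A 0.82, ND-MLRQ 0.79) and 11 lower (ATPsynB −0.62), 14 and 11 adjusted over the list alone. Of 85 cytosolic ribosomal protein genes 2 rose and 9 fell, but 1 rose and 0 fell adjusted over the list alone. The falls over all genes included RpLP0 (−0.42), RpL22 (−0.42) and RpS9 (−0.39).

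Some homeotic and patterning genes that are common Polycomb targets rose from low levels in GAF RNAi. Antp rose from 1.79 ± 0.995 to 8.15 ± 2.91 CPM, Scr from 0.0382 to 0.508 CPM and Ubx from 0.415 to 1.54 CPM, 3 of 6 Hox genes tested (3 adjusted over the list alone, median 1.99). Of 20 further patterning genes 8 rose and 1 fell (10 and 1 adjusted over the list alone, median 1.63, also with ftz at its bound), with ftz going from no counts to 1.62 ± 0.17 CPM (at least 77.6-fold), salm up by 2.06, disco by 2.77, vg by 3.64 and hth at −0.47. The camera adjusted p values were 0.0381 and 0.00224, and adjusted p = 0.451 for both with an estimated correlation. The call of Ubx was lost with library size only (edgeR adjusted p = 0.0504), limma-voom (0.0629) or all 14 libraries in 1 fit (0.113). It was also lost without control replicate 1 (0.0812), 2 (0.0518) or 3 (0.0998), or RNAi replicate 1 (0.0654) or 3 (1.24, 0.257). The Hox list was lost without GAF control replicate 1 (adjusted p = 0.094), and the patterning list when only genes of at least 5 CPM were tested (median −0.03, adjusted p = 0.951). Of 11 optic lobe and disc genes 3 rose and 2 fell (4 and 2 adjusted over the list alone), with dac at 1.88 and ap at 1.78. Of 9 germline genes 3 rose (bam 1.65, AGO3 1.23, aub 1.05) and gcl fell by 0.9, the same numbers adjusted over the list alone. Of 23 Polycomb group genes jing rose (0.92) and esc (−0.83) and Pcl (−0.68) fell. Of 23 Trithorax group genes skd rose (0.65), and of 13 histone acetylation genes ear (0.67) and mof (0.56) rose. These counts were the same adjusted over the list alone. The third member past the threshold in the last list, CBP (−0.72), encodes in the reference a calcium-binding protein and not the acetyltransferase nej. Of 21 insulator and GAGA partner genes 3 rose and 2 fell, the same numbers adjusted over the list alone, with Ibf2 (0.69) and E(bx) (0.41) up and corto (−0.71) and Nurf-38 (−0.53) down. In edgeR 0 of 19 histone deacetylase complex genes passed, also adjusted over the list alone (6 at an unadjusted p under the threshold, 2 by DESeq2 and 0 by limma-voom), with Caf1-55 at −0.15 ± 0.12 and CtBP at −0.09 ± 0.11.

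Of 25 apoptosis and stress genes in GAF RNAi 8 fell and 1 rose (8 and 1 adjusted over the list alone), while 16 were not called and the list did not pass (median −0.04, camera adjusted p = 0.206). GstD1 fell from 704 ± 91.4 to 137 ± 59.7 CPM, the insulin-like peptide gene Ilp8 by 2.61 and Gadd45 by 1.4 on the log2 scale, while the cell death gene skl rose from 2.59 ± 0.523 to 21.2 ± 5.8 CPM. Of 18 heat shock genes Hsp23 (0.86) and Hsp27 (0.67) rose and Hsc70-4 (−0.88) and Hsp83 (−0.38) fell (1 and 2 adjusted over the list alone). Hsp23 passed narrowly (edgeR adjusted p = 0.0496, but 0.0509 with RLE factors, 0.0537 with library size only and 0.2 without a filter), and DESeq2 (0.00061) and limma-voom (0.0099) called it too. It did not pass in edgeR without control replicate 2 (0.141) or 3 (0.0691), or without RNAi replicate 1 (0.179), 2 (0.0644) or 3 (0.123). Of 7 immune genes PGRP-SA (−3) and Rel (−0.81) fell, and both did so adjusted over the list alone. The marker genes carried by many transgenes also differed, v rising from 0.0284 to 1.75 ± 0.216 CPM and y from 0.149 to 1.77 ± 0.484 CPM, 2 of 3 (2 adjusted over the list alone, median 3.58, camera adjusted p = 0.0398, adjusted p = 0.469 with an estimated correlation). That list was lost without GAF control replicate 1 (adjusted p = 0.0572), control replicate 3 (0.0573) or RNAi replicate 3 (0.0647).

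HDAC1 RNAi gave few changes past the threshold, all of them falls. The receptor gene mthl8 fell from 25.9 and 16.9 CPM in the controls to no counts in either library (at least 555-fold, edgeR adjusted p = 0.00168), and ImpE2, an ecdysone-inducible gene, from 2.42 and 5.05 CPM to no counts (at least 98-fold). CG15212 fell from 10.8 and 28.6 to 0.0429 and 0.0634 CPM, nompC, a mechanosensory channel gene, from 19.9 and 13 to 0.172 and 0.602 CPM, and pio, an apical matrix gene, from 68.5 and 97.1 to 1.89 and 7.23 CPM. The others were CG9452 (−5.88), lncRNA:CR45665 (at least 63.7-fold lower), hui (−3.19), nw (−2.66) and CG10512 (−2.58). Whether these falls reflect HDAC1 or the genetic background of the cross was not tested. The transgene marker gene v also differed, with 6 and 6 counts in the controls and 145 and 49 in the libraries labelled HDAC1 RNAi. edgeR called 10 of 10299 genes lower and 0 higher, where 1222 had an unadjusted p under the threshold. DESeq2 called 294, 162 of them higher, and limma-voom 2, with 0 higher. The libraries labelled HDAC1 RNAi lay further apart than any other replicate pair, with a correlation of log2 CPM of 0.972 against 0.993 to 0.996. Without replicate 1 the count was 1627 and without replicate 2 it was 3621, both under the assumption that the remaining RNAi library varies like the controls. Without control replicate 1 or 2 it was 36 or 43, and with library size only it was 0. It was 309 without a filter, 170 of them higher, and 345 in a fit of all 14 libraries, 217 of them higher. In that fit 6 of the 10 calls were kept.

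In the fixed lists, edgeR called 0 of 633 members in HDAC1 RNAi over all genes, with 69 higher and 29 lower at an unadjusted p under the threshold, 25 and 10 by DESeq2 and 0 by limma-voom. Several lists passed camera at the preset correlation, but none passed fry or camera with an estimated correlation. Adjusted over the list alone, 9 of 12 progenitor genes, 9 of 13 early neuron genes and 15 of 22 mature neuron genes rose and 5 of 20 stem cell genes fell. The list medians were 1.53, 1.36, 1.25 and −0.86, with camera adjusted p of 7.1e-09, 2.31e-09, 8.07e-13 and 4.88e-06, and adjusted p = 0.736 for each with an estimated correlation. In the libraries labelled replicate 1 and 2 the progenitor median lay 2.15 and 0.82 above the control mean, and the mature neuron median 1.63 and 0.88. Without RNAi replicate 1 the progenitor list stood at 0.79 (camera adjusted p = 0.00174). Single values ran from 494 and 591 CPM in controls to 1876 and 1516 for pros (edgeR adjusted p = 0.193), from 91.7 and 74.4 to 253 and 173 for elav (0.232), from 10.7 and 5.3 to 35 and 15.8 for erm (0.233), and from 9.01 and 4.71 to 33 and 6.34 for ase (0.413). Values of pnt went from 528 and 494 to 92.7 and 218 CPM (0.217), and those of dpn from 8.66 and 8.2 to 6.69 and 2 CPM (0.6).

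Ribosomal protein genes had a median of −0.68 in HDAC1 RNAi (camera adjusted p = 1.3e-12, adjusted p = 0.941 with an estimated correlation), ribosome biogenesis genes −0.55 (3.28e-05, adjusted p = 0.736 with an estimated correlation) and oxidative phosphorylation genes −0.31 (0.000515, adjusted p = 0.987 with an estimated correlation). The oxidative phosphorylation median was −0.98 in replicate 1 and 0.04 in replicate 2, and the list turned to 0.06 without replicate 1 and was lost without control replicate 1 (−0.19, adjusted p = 0.0703), while without replicate 2 it stood at −1 (2.56e-16). The share of mitochondrial genome counts also differed, 2.36% in replicate 1 and 0.24% in replicate 2 against 0.57% and 0.37% in the controls. Notch pathway genes (median 0.47, camera adjusted p = 0.000822) and muscle genes (−1.56, 0.00608) passed as well, each with adjusted p = 0.736 with an estimated correlation. Adjusted over the list alone, 5 of 30 Notch pathway genes rose and 0 of 10 muscle genes passed in edgeR, where 2 had an unadjusted p under the threshold and DESeq2 and limma-voom called 0. The muscle list was lost without control replicate 1 (median −0.56, adjusted p = 0.204) and without RNAi replicate 1 (−0.97, 0.256), and also with a mean of at least 5 CPM (−1.52, 0.0834) and in a fit of all 14 libraries (−1.55, 0.0655), while without RNAi replicate 2 it stood at −2.52 (0.0215). The Notch list was lost without control replicate 2 (0.2, 0.114), without RNAi replicate 2 (0.46, 0.062) and in a fit of all 14 libraries (0.54, 0.0655), while without control replicate 1 it stood at 1.08 (1.39e-05). The other 21 lists did not pass camera in the HDAC1 experiment. With library size only, the median of all genes moved from 0.06 to 0.33, and signs of 6 lists that did not pass turned with it.

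In the libraries labelled Osa overexpression, ribosomal protein and oxidative phosphorylation genes were lower and progenitor and early neuron genes were higher. Whether these changes reflect Osa, the mix of collected cells or the genetic background of the cross was not tested. Sema5c, a semaphorin, fell from 50.8 ± 11.8 to 2.35 ± 0.226 CPM (21.6-fold, n = 2 and 2, edgeR adjusted p = 0.000106), the zinc transporter gene ZnT41F by 3.66, the cuticle genes Cpr76Bc by 3.23 and Cpr64Ac by 3.05, CHKov1 by 2.89, GstD9 by 2.85 and tld by 2.69 on the log2 scale. Thor, the 4E-BP translation inhibitor, fell from 346 ± 134 to 49.6 ± 28.4 CPM. Among named genes of at least 10 CPM in the higher group, the largest rises were those of the neuropeptide gene Ms (0.664 ± 0.438 to 17.5 ± 6.68 CPM, 26.4-fold), drm (3.21), the homeobox genes bsh (2.93) and Rx (2.85), jar (2.74), the neuropeptide gene Mip (2.39), Trh (2.35) and the temporal factor cas (46.8 ± 1.05 to 230 ± 104 CPM). Of 9156 genes tested 1929 changed, 811 higher and 1118 lower, so 42% of the changed genes were higher. With library size only, 1963 of 2501 changed genes were higher (78.5%) and the median of all genes moved from 0.05 to 0.32, so directions below are relative to TMM scaling. The count fell to 354 in a fit of all 14 libraries and to 498 or 572 without control replicate 1 or 2, and rose to 3535 without overexpression replicate 2. Of 104 named genes that changed, 29 kept their call in the fit of all 14 libraries, 53 without control replicate 1 and 63 without control replicate 2.

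Progenitor genes rose in Osa overexpression, 10 of 11 (10 adjusted over the list alone, median 1.62, camera adjusted p = 1.42e-14). erm rose from 12.3 ± 4.62 to 59.6 ± 21.2 CPM, ase from 61.5 ± 14.9 to 213 ± 9.32, D from 95.6 ± 14.6 to 294 ± 38.3 and opa from 41.4 ± 4.37 to 149 ± 59.1. Of 13 early neuron genes 8 rose (8 adjusted over the list alone, median 0.74, camera adjusted p = 1.96e-06), among them nerfin-1 (1.71), Hey (1.84), pdm3 (1.37) and pros (169 ± 59.8 to 436 ± 45.3 CPM). Of 22 mature neuron genes 5 rose (5 adjusted over the list alone, median 0.38, camera adjusted p = 0.00433), including elav (0.62), nSyb (0.81), onecut (0.9) and Appl (0.96), and this list was lost without control replicate 2 (0.16, adjusted p = 0.0624) and stood at 0.62 without control replicate 1. Of 20 stem cell genes 8 fell and 2 rose (8 and 4 adjusted over the list alone, median −0.33, camera adjusted p = 6.62e-05). The lower ones included grh (358 ± 26.6 to 116 ± 11 CPM), pnt (357 ± 8.48 to 116 ± 25.2 CPM), Six4 (−1.52) and tll (−1.22), while dpn did not pass (−0.31 ± 0.21, edgeR adjusted p = 0.321). Each of these 4 lists had adjusted p = 0.509 with an estimated correlation. The stem cell median was −0.22 without control replicate 2 and −0.54 without overexpression replicate 2. Of 14 temporal patterning genes 4 fell and 2 rose, the same numbers adjusted over the list alone, with Imp down from 1960 ± 238 to 631 ± 144 CPM, Syp by 1.4 and svp by 1.54 on the log2 scale.

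Ribosomal protein and oxidative phosphorylation genes fell broadly in Osa overexpression, and parts of other metabolic lists fell. Of 85 cytosolic ribosomal protein genes 81 fell (81 adjusted over the list alone, median −0.81, camera adjusted p = 5.38e-41), such as RpS20 (−0.93 ± 0.14), RpS26 (−0.92), RpS4 (−0.91) and RpL14 (−0.86). Of 69 oxidative phosphorylation genes 50 fell (58 adjusted over the list alone, with 1 higher, median −0.63, camera adjusted p = 1.59e-17), such as ND-19 (−0.94) and ND-PDSW (−0.89). Glycolysis genes fell for 4 of 12 (4 adjusted over the list alone, median −0.42, camera adjusted p = 0.00116), Pglym78 (−1.11), Gapdh1 (−1.1), Tpi (−0.82) and Ldh (−0.74). Mitochondrial genome genes fell for 5 of 16 (7 adjusted over the list alone, median −0.77, camera adjusted p = 0.000209), such as ND5 (−1.12) and COX1 (−0.9). Of 29 ribosome biogenesis genes 10 fell and 1 rose (13 and 1 adjusted over the list alone, median −0.27, camera adjusted p = 0.00112), with mod at −0.82 and eIF6 at −0.73, and with library size only this median was 0.01. These 5 lists had adjusted p = 0.509 with an estimated correlation, and the glycolysis list was lost without control replicate 1 (−0.21, adjusted p = 0.0683) and stood at −0.27 without overexpression replicate 2. The mitochondrial genome median was −1.08 in overexpression replicate 1 and −0.43 in replicate 2, and −0.45 without control replicate 1 or −0.44 without overexpression replicate 1. These transcripts made up 6.01% and 5.53% of counts in the controls and 4.12% and 5.82% in the overexpression libraries. Without overexpression replicate 1 the ribosome biogenesis median was −0.44. With library size only, COX1 (−0.63, edgeR adjusted p = 0.0803) and Ldh (−0.46, 0.0834) no longer passed. Nor did they in a fit of all 14 libraries (0.342 and 0.307), without control replicate 1 (−0.67, 0.179 and −0.45, 0.279) or without overexpression replicate 1 (−0.57, 0.0577 and −0.72, 0.0726).

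Cell cycle genes rose for 11 of 40 (11 adjusted over the list alone, median 0.21, camera adjusted p = 0.021), including Klp61F (0.82), pav (0.91), Orc1 (0.89) and Mcm5 (0.76). Heat shock genes rose for 6 of 18 (7 adjusted over the list alone, median 0.28, camera adjusted p = 0.0102), with Hsp68 at 0.67 and stv at 1. The near-identical Hsp70Bb and Hsp70Bc stood at 0.77 and 0.74, and their reads cannot be assigned with certainty. Polycomb group genes rose for 5 of 23 (5 adjusted over the list alone, median 0.34, camera adjusted p = 0.00836), Scm (0.98), Jarid2 (0.7), Su(z)12 (0.7) and jing (0.61) among them. The 3 lists had adjusted p = 0.509 with an estimated correlation, and the heat shock list was lost without control replicate 2 (0.23, adjusted p = 0.0761). Without control replicate 1 it stood at 0.44, and without overexpression replicate 1 the Polycomb group list stood at 0.21. Of 23 Trithorax group and SWI/SNF genes, osa itself, mor (1.32), Bap60 (0.55) and 1 more rose and ash2 (−0.64) fell, the same numbers adjusted over the list alone. In this list ash2 did not pass with library size only (−0.36, edgeR adjusted p = 0.0885), all 14 libraries in 1 fit (0.0822), or without control replicate 1 (0.184) or 2 (0.068). Of 19 histone deacetylase complex genes 3 rose, ebi (0.85), MTA1-like (0.77) and HDAC1 (282 ± 9.28 to 389 ± 23.8 CPM), with 1 adjusted over the list alone. Of 13 histone acetylation genes 4 rose (5 adjusted over the list alone), including Ada3 (1.03), Gcn5 (0.85) and Ada2a (0.78), and CBP, the calcium-binding protein gene, fell by 0.49. Insulator and GAGA partner genes split into 8 higher, such as mod(mdg4) (0.86) and zf30C (0.85), and 2 lower, corto (−0.86) and Nurf-38 (−0.61), of 21 (10 and 2 adjusted over the list alone). The calls of CBP and Nurf-38 were lost with library size only (−0.21, edgeR adjusted p = 0.253 and −0.33, 0.0706), all 14 libraries in 1 fit (0.443 and 0.123), or without control replicate 1 (0.276 and 0.0931) or 2 (0.208 and 0.132).

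The remaining lists did not pass camera in Osa overexpression. Of 29 Notch pathway genes 4 rose, E(spl)m6-BFM (1.76), mib1 (1.41), E(spl)m3-HLH (1.09) and numb (0.67). Of 24 asymmetric division genes 4 rose, pros and numb with Klp10A (0.78) and pon (0.61). In both lists 4 rose adjusted over the list alone. Of 25 apoptosis and stress genes 4 rose and 5 fell (6 and 7 adjusted over the list alone), with skl (1.77) and egr (0.93) up and GstD1 (−1.03) and Dcp-1 (−0.94) down. Of 19 glia genes 3 rose and 2 fell (4 and 2 adjusted over the list alone), with Gs2 (2.27) and nrm (0.72) up and Tret1-1 (−1.01) down. The glia median was 0.72 (camera adjusted p = 0.0907), close to that of the early neuron list, with 17 and 15 members above the control mean in the overexpression libraries. He of blood cells went from no counts to 0.948 ± 0.543 CPM (at least 19-fold), 1 of 10, and Lsp1gamma of the fat body fell by 1.52, 1 of 4, each also adjusted over the list alone. DESeq2 called 0 blood cell genes and limma-voom 1. The blood cell median was 1.09 (camera adjusted p = 0.0705), with 10 and 8 members above the control mean. Of 14 optic lobe and disc genes ap rose (2.09) and hth (−0.75) and ct (−0.59) fell (3 and 3 adjusted over the list alone). Of 26 patterning genes run (2.07) and tup (1.54) rose and hth fell, and of 7 Hox genes Ubx fell (−1.56). These 2 lists had the same numbers adjusted over the list alone. With library size only hth (−0.47, edgeR adjusted p = 0.0522), ct (−0.32, 0.191) and Ubx (−1.28, 0.0715) no longer passed. Without control replicate 1 or 2 neither hth (0.0965 and 0.0533) nor ct (0.253 and 0.0959) passed. Without overexpression replicate 1 ct was lost (−0.36, 0.0913), and without control replicate 1 Ubx was (−0.97, 0.294). Ubx also did not pass in limma-voom (0.0562), nor ct and Ubx in a fit of all 14 libraries (0.14 and 0.321). The eye pigment gene w, a transgene marker, rose by 0.58, a call that DESeq2 also made and limma-voom did not. No muscle, germline or immune gene passed in edgeR, also adjusted over the list alone (2 germline genes at an unadjusted p under the threshold, 1 by DESeq2 and 0 by limma-voom): Mef2 stood at −0.37 ± 0.25, Act57B at 0.06 ± 0.28, stau at −0.27 ± 0.14, gcl at 0.11 ± 0.2, AttB at 0.53 ± 0.85 and Rel at 0.04 ± 0.18.

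**Figure D2:**
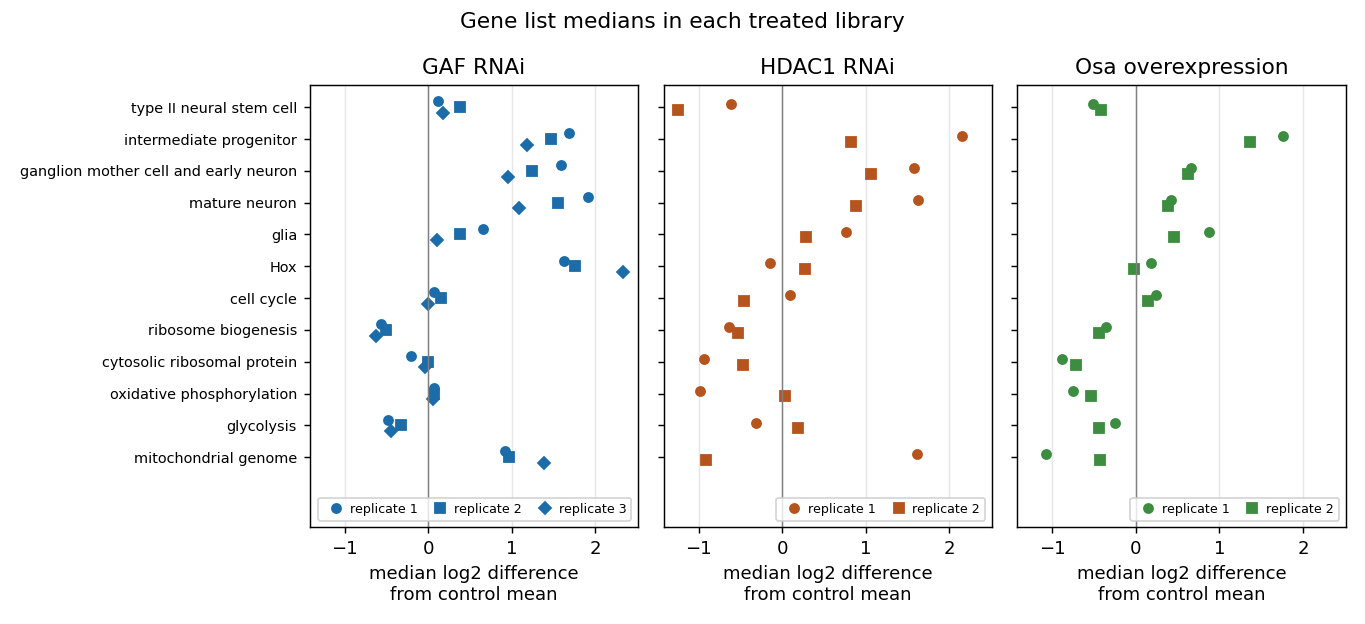
Median log2 difference from the mean of the control libraries over the members of 12 gene lists, for each treated library (TMM scaling; marker shape gives the replicate). Intermediate progenitor medians are 1.69, 1.47 and 1.18 in GAF RNAi, 2.15 and 0.82 in HDAC1 RNAi, and 1.76 and 1.37 in Osa overexpression, while ribosomal protein medians are −0.88 and −0.72 in Osa overexpression.

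The experiments were then compared with each other. Controls of the HDAC1 experiment differed from the other controls at baseline, with mitochondrial genome shares of 0.57% and 0.37% against 5.53% to 7.41%. Whether comparisons with HDAC1 RNAi depend on this baseline difference was not tested. Genes lower in both GAF RNAi and Osa overexpression numbered 334 of 8482 tested in both, where independent lists would share 186 (one-sided Fisher's exact p = 6.4e-33), and genes higher in both numbered 134 against 94.3 (7.76e-06). These p-values treat genes as independent units, so they do not measure the spread between libraries. Another 162 genes were called in opposite directions. With library size only the balance turned, with 174 genes lower in both and 291 higher in both. In a fit of all 14 libraries 65 genes were lower in both and 12 higher in both. The response itself differed between GAF RNAi and Osa overexpression for 321 of 11181 genes and between GAF RNAi and HDAC1 RNAi for 358, while edgeR found 1 gene between HDAC1 RNAi and Osa overexpression, where 907 had an unadjusted p under the threshold and DESeq2 called 74. These counts depended on single libraries. The 321 became 196 or 193 without GAF control replicate 2 or 3, 199 without GAF RNAi replicate 1, 148 or 130 without Osa control replicate 1 or 2, and 110 without Osa overexpression replicate 1. The 358 became 212 without GAF control replicate 3, 234 or 238 without GAF RNAi replicate 1 or 3, 136 or 145 without HDAC1 control replicate 1 or 2, and 806 or 2772 without HDAC1 RNAi replicate 1 or 2. The count of 1 became 850 or 488 without HDAC1 RNAi replicate 1 or 2, and 2 without HDAC1 control replicate 2 or Osa control replicate 1. The ribosomal protein list lay 0.72 higher in GAF RNAi than in Osa overexpression (camera adjusted p = 1.68e-17), the mature neuron list 1.01 (0.000106) and the mitochondrial genome list 1.75 (6.11e-06), each with adjusted p = 0.738 with an estimated correlation. In GAF RNAi the stem cell list lay 0.61 higher than in HDAC1 RNAi (camera adjusted p = 2.74e-06, adjusted p = 0.314 with an estimated correlation) and the ribosomal protein list 0.52 (4.68e-12, adjusted p = 0.685 with an estimated correlation). The mature neuron list lay 0.93 higher in HDAC1 RNAi than in Osa overexpression (1.26e-05, adjusted p = 0.683 with an estimated correlation) and the blood cell list 1.43 lower (0.0013, adjusted p = 0.436 with an estimated correlation). Over genes, which are not independent replicates, the log2 fold changes correlated with Spearman's rho of 0.499 between HDAC1 RNAi and Osa overexpression, 0.249 between GAF RNAi and HDAC1 RNAi and 0.167 between GAF RNAi and Osa overexpression. The first of these was 0.205 without HDAC1 RNAi replicate 1, and the second was 0.155 without HDAC1 RNAi replicate 2.

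**Figure D3:**
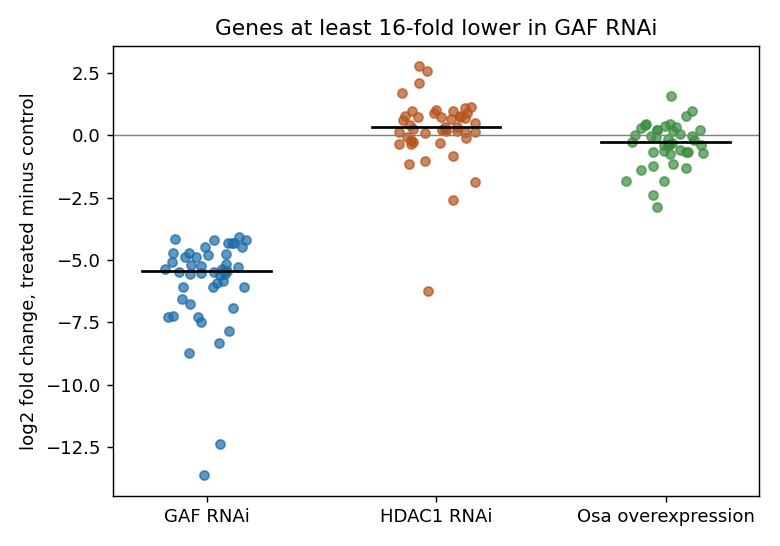
Fitted log2 fold change (treated minus control) of the 47 genes at least 16-fold lower in GAF RNAi, in each experiment, with a line at the median; fitted values of genes with no counts depend on a prior count. Medians are 0.32 in HDAC1 RNAi (45 genes tested) and −0.25 in Osa overexpression (41 genes tested).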

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

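All tests of explanations in this part were chosen after the results were seen, except the count over other splits of the GAF libraries.

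Named genes changed in opposite directions in GAF RNAi and Osa overexpression, with the difference past its own edgeR test, in 7 cases. The cuticle genes Ccp84Ab and Cpr64Ac differed by 8.95 ± 1.43 and 4.31 ± 0.81 (log2, GAF minus Osa), being higher in GAF RNAi (3.68 and 1.28) and lower in Osa overexpression (−5.3 and −3.05). Syp, a temporal RNA-binding protein gene, differed by 1.8 ± 0.26 (0.42 against −1.4, edgeR adjusted p = 0.00157). The respiratory chain genes COX2, COX7A and ND-MLRQ differed by 1.75 ± 0.33, 1.56 ± 0.29 and 1.35 ± 0.28, and Lsp1gamma by 2.38 ± 0.51.

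The libraries labelled HDAC1 RNAi differed from each other. A control library under the label of replicate 1 is argued against by v, which stood 23.2-fold above both controls (counting interval 12.9 to 46). RNA from another experiment is argued against by genes private to those experiments. In replicate 1 the summed level of 2 private to the Osa experiment was 0.0708% of that in their own libraries (upper bound 0.394%), and that of 2 private to the GAF experiment 0.035% (0.126%). A weaker knockdown as the whole cause would place replicate 1 nearer the controls. Its spread of differences from the controls was instead 1.27 times wider than that of replicate 2 (bootstrap interval over 6705 genes 1.24 to 1.3). That interval does not cover variation between libraries, and the spread takes in any shift from preparation. Whether the knockdown was weaker in replicate 1 therefore stays open, and HDAC1 itself was less reduced there. A bias in library preparation stays open and could not be tested directly, since no batch is given. Over 6738 genes, replicate 1 minus replicate 2 correlated at 0.65 with Osa minus HDAC1 controls and at 0.45 with GAF minus HDAC1 controls. This difference does not tell which of the 2 replicates moved. In log2 CPM, Osa control replicate 1 correlated at 0.958 and 0.925 with HDAC1 RNAi replicates 1 and 2. Its correlations with the HDAC1 controls were 0.95 and 0.949. GAF control replicate 1 correlated at 0.918 and 0.898 with the RNAi replicates, and at 0.935 and 0.937 with the HDAC1 controls. A shift of replicate 1 itself towards both experiments was therefore not shown.

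Progenitor and neuron transcripts were higher in GAF RNAi. Scaling, which moves all genes of a library alike, is argued against by the median of the 3 lists (45 genes) lying 1.41 above that of the other 9010 tested genes (interval 1.12 to 1.59). Under a lower share of stem cells with all other brain cells alike, neuron and glia genes would rise alike. Among genes with a mean under 20 CPM, the neuron median lay 1.35 above the glia median (interval 0.23 to 1.75, 16 and 13 genes). The interval treats genes as independent, but the mature neuron list had an estimated correlation of 0.503. It is therefore too narrow, and this explanation is weakened but not excluded. More progeny among the collected cells, or progenitor and neuron genes turned on within stem cells, cannot be told apart, because the lists rose in each RNAi library (lowest median 0.96) under either and no cell-level data were used here. The biological reading is therefore only a hypothesis.

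Genes close to loss in GAF RNAi, 47 at least 16-fold lower, may reflect GAF itself or the genetic background of the cross. A background common to the RNAi crosses and absent from the HDAC1 controls would lower these genes in HDAC1 RNAi too. Their median of 0.32 there (interval 0.14 to 0.71, 45 genes) argues against it for the set as a whole. It is not argued against for the 5 of 45 at least 2-fold lower there. In Osa overexpression 8 of 41 were so. The control lines are not described in the sources used here, so a background that the HDAC1 controls also carried would escape this test. A background private to the GAF-RNAi cross stays open: the genes did not concentrate on a chromosome arm (permutation p = 0.306), which a mixed background would also give, and no genotype data were used here. In the same libraries 37 genes were at least 16-fold higher.

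Splitting the 6 GAF libraries otherwise into 3 and 3 gave at most 0 changed genes by edgeR, against 2573 in the real split, the 1 split of 10 with as many; 10 splits are too few for a share under 0.05.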

How the results depend on the processing

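The counts divided by 2 were chosen after the data were seen. The other alternatives were planned, except that fry was not among the fixed list tests. No changed gene turned its sign in a setting that tested it. A mean of at least 5 CPM left 637, 3 and 113 changed genes untested in GAF RNAi, HDAC1 RNAi and Osa overexpression. The self-test recovered 3% of 2-fold changes in the HDAC1 experiment and 59% in the Osa experiment, at the same group size and similar depth. The common biological coefficient of variation was 0.39 in the former and 0.216 in the latter. Lower depth was tried only as counts divided by 2. Where a setting changes the genes or libraries tested, that is part of the cause; otherwise the cause was not tested. A library left alone in its group was assumed to vary like the other groups.

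Changed genes in GAF RNAi (2573) numbered 1451 with all 14 libraries in 1 fit, 1090 at 2-fold or more, and 1593 to 3389 with a library left out. In HDAC1 RNAi (10) they numbered 0 with library size only, 309 without a filter, 294 with DESeq2, 2 with limma-voom, 345 with all libraries, 38 with counts divided by 2 and 36 to 3621 with a library left out. In Osa overexpression (1929) they numbered 354 with all libraries, 568 at 2-fold or more and 498 to 3535 with a library left out. Of 106, 10 and 104 named genes that changed, the calls kept with all libraries in 1 fit numbered 77, 6 and 29, and those kept with a library left out 87 to 101, 7 to 9 and 53 to 97. The HDAC1 fold change ranged from −1.09 to −0.32 with a library left out, osa was 0.99 with all libraries (edgeR adjusted p = 0.0642; from 0.961 to 1.01 with a library left out), and the oxidative phosphorylation median in HDAC1 RNAi (−0.31) ranged from −0.996 without RNAi replicate 2 to 0.057 without RNAi replicate 1. Lists past camera numbered 9, 9 and 12, each 0 with an estimated correlation, and with fry 11, 0 and 0. In the GAF experiment fry also passed muscle and asymmetric division genes, which camera did not.

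Genes whose response differed between GAF and HDAC1 RNAi (358) numbered 559 without a filter, 776 with DESeq2 and 136 to 2772 with a library left out. For GAF RNAi and Osa overexpression (321) these were 730, 1207 and 110 to 449. For HDAC1 RNAi and Osa overexpression (1) they were 45, 74 and 1 to 850, and 8 at a mean of 5 CPM.

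For GAF and HDAC1 RNAi, genes higher in both, lower in both and opposite numbered 61, 21 and 20 without a filter, 75, 24 and 18 with DESeq2, and 92, 29 and 17 with all libraries; the lower count was 0 with library size only, limma-voom or at 2-fold. For GAF RNAi and Osa overexpression they were 12, 65 and 7 with all libraries and 38, 41 and 17 at 2-fold; library size only gave 291 higher and 174 lower, no filter 212 higher and 253 opposite, and DESeq2 216 higher. For HDAC1 RNAi and Osa overexpression they were 74, 45 and 6 without a filter and 69, 50 and 3 with DESeq2; all libraries gave 10 higher and 66 lower, RLE 4 lower, and library size only or limma-voom 0 lower. Spearman's rho without a filter and with all libraries was 0.115 and 0.178 for GAF and HDAC1 RNAi, 0.079 and 0.107 for GAF RNAi and Osa overexpression (0.099 at 5 CPM), and 0.242 and 0.359 for HDAC1 RNAi and Osa overexpression (0.617 at 5 CPM).

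Equal replicate numbers did not pair the GAF samples: deviations of same-numbered libraries correlated at −0.004, −0.084 and −0.197. In the HDAC1 and Osa experiments they correlated at 0.165 and 0.009, but with 2 pairs both pairs give the same value by construction, so pairing there stays open. With the replicate number as a block, changed genes numbered 2344, 241 and 1827 in GAF RNAi, HDAC1 RNAi and Osa overexpression. Under this block, genes higher in both, lower in both and opposite were 41, 19 and 17 for GAF and HDAC1 RNAi and 33, 33 and 2 for HDAC1 RNAi and Osa overexpression, and 2 genes differed in response between the last pair.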

Other observations

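The tests in this part were chosen after the results were seen.

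The libraries of the HDAC1 experiment differed from the others at baseline, and not only in His3.3B and Cdc42. The most abundant transcript was lncRNA:CR34335 in each HDAC1 library. In the others it was lncRNA:cherub, except for lrRNA in Osa overexpression replicate 2. Mitochondrial genome transcripts made up 0.24% to 2.36% of counts in the HDAC1 experiment, against 4.12% to 11% in the GAF and Osa experiments. His3.3B, a replacement histone gene, stood at 227 and 175 CPM in the HDAC1 controls, 236 in HDAC1 RNAi replicate 2 and 1300 in replicate 1, against 2950 to 5170 in the GAF and Osa experiments. Cdc42 stood at 37.4, 34.1, 33.8 and 132 CPM, against 420 to 653; both genes were chosen after their values were seen. Over 6738 genes, which are not independent replicates, the difference between the libraries labelled HDAC1 RNAi replicate 1 and 2 correlated at 0.65 with the difference between Osa and HDAC1 controls and at 0.45 with that between GAF and HDAC1 controls. The differences compared share no library, and they do not tell which of the 2 replicates moved. Of 14 genes on in the other HDAC1 libraries and off in the Osa experiment, 13 were still on (at least 1 CPM) in replicate 1.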
